A study of Mus musculus with 18 samples.

How the data were processed

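RNA from 18 samples of BV2 cells was sequenced, 3 libraries for each combination of 2 line labels (NC and BAK1-KD) and 3 times of oxyhemoglobin (0 h, called control, 12 h and 24 h). Per the labels' protocols, cells were plated 12 h before treatment, and libraries were made from total RNA with a tagmentation kit. Whether the libraries kept strand information is not given in the sources used here. The deposited series held a table of read counts per gene and a table of TPM for the same 55487 genes. Per the submitters' processing notes, the authors used bcl2fastq, HISAT2 2.2.0, featureCounts and DESeq2 and the GRCm38 build. The counts were deposited as whole numbers and not normalized, and 28940 genes had at least 1 count in any library. The deposited TPM equalled the deposited counts divided by the deposited gene length and rescaled, to within 4.89e-05. A further check found 114 symbols that stood on more than 1 gene ID, and genes were therefore handled by ID. Positions came from GENCODE M21, on the same build but not named as the authors' release, where 55227 of the 55487 IDs were found.

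Groups and library numbers came from the sample titles. Library totals ran from 4361313 to 6008810 counts. No pair of libraries within a group agreed within counting noise (chi-square per degree of freedom 4.98 to 19.6), so none was taken for a copy of another, and each of the 18 was counted as a sample, which does not show separate cultures. Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with TMM factors, filterByExpr (minimum count 10), 1 mean per group, all 18 libraries sharing the estimate of spread, and robust fitting. The 15996 genes tested held 99.65% of the counts, with a median biological coefficient of variation of 0.232. Fold changes are log2, with standard errors, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The 12 comparisons were the lines at each time and averaged over times, the times within each line, and the interactions of line with 12 h and 24 h.

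Gene lists, 31 in all with 532 genes of which 420 were tested, were fixed before the data were examined. They covered the Bcl2 family, the necroptosis pathway, apoptosis execution, inflammasome and pyroptosis, inflammatory mediators, NF-kB targets, interferon response, heme and iron handling, NRF2 targets, ferroptosis, integrated stress and ER stress, heat shock, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded genes, G2/M and mitosis, DNA replication, cholesterol synthesis and uptake, homeostatic and disease-associated microglia, alternative activation, lysosome and autophagy, p53 targets, antigen presentation, immediate early genes, cytosolic ribosomal proteins, and markers of erythroid cells, neurons, astrocytes, oligodendrocytes, and fibroblasts and endothelium. The 30 lists with at least 2 tested members were tested with camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over lists, and again with an estimated correlation and with fry. Some genes stand on more than 1 list.

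Genes named in the text followed a rule fixed before the data were examined. Bak1 was always named, as was a panel of death, inflammation and heme genes in any comparison. In each comparison the rule took the 6 largest changes in each direction among genes past the threshold whose replicates did not overlap and whose mean was at least 5 CPM in the higher group (10% of 3-against-3 splits give groups that do not overlap by chance). For averages and interactions the overlap condition was dropped and the mean of the highest group used. It also took up to 4 members of each list with the lowest adjusted p.

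The alternatives were RLE and upper-quartile factors, no filter (28940 genes), a filter of 5 CPM in 3 libraries (12368 genes), DESeq2 1.42.0, a replicate block, a fit of the compared groups alone, and limma-trend on log2(TPM + 1) or log2(TPM + 0.1) with and without a filter of mean TPM 1 (16490 genes). Each library was also left out in turn. A fold against a group with no counts was bounded with 3 counts over the group, and with 1 to 3 counts the ratio of count rates is given with its exact 95% interval. The library numbers were checked as pairs by correlating deviations from group means between libraries with the same number. Every pair passed 0.1 in the comparison of the lines at 12 h and in the 6 comparisons of times within a line, and for those the values with the block are given beside the results, while the tests themselves stayed without it. The lowest values in the comparisons of the lines were 0.07 at control and 0.095 at 24 h, and there the block is left to the part on processing choices. The labels do not say what a number stands for.

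The procedure was tested on simulated counts for 15996 genes with 100 genes changed by each size. Of changes of 1 and 2 on the log2 scale, it recovered 81 and 99% for the average of the lines, 30 and 86% for the lines at control, 38 and 89% for NC 12 h against control, and 7 and 72% for the 12 h interaction. False calls there were 11, 6, 3 and 5 (5.76, 4.92, 2.31 and 5.95% of calls), and simulated comparisons without change gave 0. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.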

Results

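The series holds RNA sequencing counts from BV2 cells, an immortalized mouse microglial line, in 2 cell lines whose labels read NC and BAK1-KD. Each line was sampled without treatment (control, 0 h) and after 12 h and 24 h of oxyhemoglobin, the oxygen-carrying blood protein, at a labelled dose of 10 mM, high for a protein and so uncertain in its unit. The labels give no untreated sample at 12 h or 24 h, so time in culture goes with treatment, and no sample tests for endotoxin in the oxyhemoglobin. The labels spell out neither NC nor KD and do not say how the second line was made. Each of the 6 groups had 3 libraries, 18 in all, and nothing in the labels says that the 3 came from separate cultures, so p-values measure only the spread between these libraries. Per library, the total counts were 5101655, 5517610 and 4818352 for NC control, 4857848, 5113493 and 5546969 for NC 12 h and 4361313, 5006300 and 6008810 for NC 24 h. The KD-labelled libraries held 4545042, 5772212 and 4937684 counts at control, 4833337, 4962349 and 4739878 at 12 h and 5955346, 4524433 and 4466642 at 24 h. Between 20896 and 22503 genes had at least 1 count in a library. A single gene, CT010467.2, took 12.89 to 25.27% of the counts, and mitochondrially encoded genes took 0.60 to 2.37%. The first principal component, with 26.3% of the variance, separated the 12 treated libraries from the 6 controls. On the second, with 14.7%, the library numbered 2 had the lowest score of each of the 6 groups. Changes are given as log2 fold changes ± SE with 3 libraries per group, unless stated, from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 15996 genes. Where leaving out 1 library changed the call of a gene list, the adjusted p without it is followed by that library's group and number, or, for the least stable lists, the number of such fits is given. Directions between the lines are given for the libraries labelled KD, because the targeted gene was not lower in them.

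Bak1 (ENSMUSG00000057789), whose protein permeabilizes the outer mitochondrial membrane in apoptosis, is the gene that the KD label names. It lies on the minus strand of chromosome 17 from 27019810 to 27029009 (GRCm38), and 25.5% of its exon bases are also exon of Ggnbp1 on the other strand. Its counts in the 3 NC libraries were 3, 3 and 0 at control, 2, 7 and 4 at 12 h, and 1, 0 and 5 at 24 h. The KD-labelled libraries had 2, 4 and 7, then 4, 1 and 5, then 12, 2 and 2. Mean levels were 0.374 ± 0.330 CPM (SD, n = 3) in NC control, 0.833 ± 0.405 in NC 12 h and 0.391 ± 0.476 in NC 24 h. They were 0.831 ± 0.549, 0.700 ± 0.456 and 0.999 ± 0.956 CPM in the KD-labelled groups at the same times. Over all times the KD-labelled libraries had 39 counts and the NC libraries 25, a ratio of count rates of 1.56 with a 95% exact interval of 0.92 to 2.69 (exact binomial test, two-sided p = 0.103). By time the ratio, with the same exact binomial test, was 2.13 (0.754 to 6.82, p = 0.167) at control, 0.783 (0.307 to 1.93, p = 0.678) at 12 h and 2.67 (0.991 to 8.32, p = 0.0347, not adjusted for the 3 times) at 24 h. An exact permutation test within times over 8000 arrangements gave a mean log2 difference of 0.76 and a two-sided p = 0.213. A library at 0 counts allows up to 0.76 CPM, taking 3 counts as the floor, so single libraries say little, and the pooled interval reached no lower than 0.92. Intervals and floors cover counting error only. The targeted gene therefore did not check the labels, and the 2 lines are compared by their labels. Ripk3 and Zbp1, which act in the necroptosis pathway, were also near the counting limit, with 5 and 4 counts in all 18 libraries together. Mlkl had 240 counts, Casp8 471, Ripk1 3146, Bcl2l1 4097, Bax 4278 and Mcl1 95829.

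**Figure D1:**
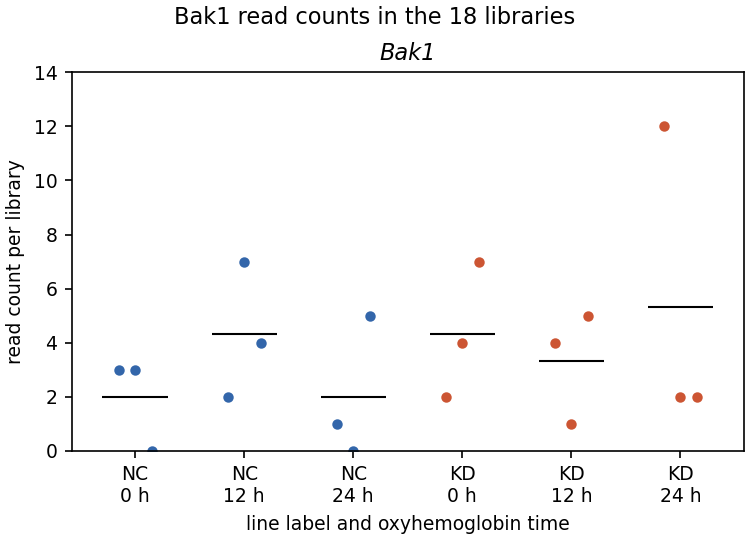
Read counts of Bak1 (vertical axis, counts per library) in the 18 libraries, by line label and oxyhemoglobin time (horizontal axis), with points for libraries and bars for group means. The counts run from 0 to 12, and the groups overlap.

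The first question was what 12 h of oxyhemoglobin changed in the NC line. Cytokines were among the genes that rose most. Csf3, the granulocyte growth factor, rose by 9.98 ± 0.43, the pyrogenic cytokines Il1b by 7.84 ± 0.37 and Il1a by 7.39 ± 0.32, and the iron-scavenging lipocalin Lcn2 by 7.39 ± 0.61. Serpina3g, one of a family of similar serpins whose reads may be shared, was at least 57.2-fold higher, and the formyl peptide receptor Fpr1 at least 27.9-fold higher, than in controls without a count. Of 18 tested inflammatory cytokines, chemokines and mediators, 16 rose and 1 fell (17 and 1 adjusted over the list alone, camera adjusted p = 9.54e-31). Among them the monocyte attractants Ccl7 and Ccl2 rose by 6.31 ± 0.23 and 3.19 ± 0.30, Il6 by 5.42 ± 0.35, Tnf by 2.62 ± 0.38, the prostaglandin synthase Ptgs2 by 3.64 ± 0.18 and the nitric oxide synthase Nos2 by 2.16 ± 0.28. Of 14 NF-kB targets 10 rose (11 adjusted over the list alone, adjusted p = 2.44e-09), among them the inhibitor Nfkbia (2.73 ± 0.22). Of 26 interferon response genes 10 rose (12 adjusted over the list alone, adjusted p = 6e-07), with Isg15 at 2.16 ± 0.19 and Gbp2 at 4.46 ± 0.40. NRF2 targets, the antioxidant programme, rose in 13 of 19 (13 adjusted over the list alone, adjusted p = 4.14e-11), led by the cystine transporter Slc7a11 (2.57 ± 0.23) and Srxn1 (2.31 ± 0.21). In heme and iron handling 8 of 19 rose and 1 fell (10 and 1 adjusted over the list alone), among them the heme oxygenase Hmox1 (2.26 ± 0.27). That call had adjusted p = 0.00165, and adjusted p = 0.156 with an estimated correlation.

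Mitosis genes fell at 12 h in the NC line. Of 20 G2/M and mitosis genes 14 fell (17 adjusted over the list alone, camera adjusted p = 5.18e-11), including the topoisomerase Top2a (-1.12 ± 0.15). Arg1, the arginase of alternatively activated macrophages, fell (-3.50 ± 0.33), as did Selenbp1 (-3.82 ± 0.48). Gm5086 was at least 33.1-fold lower. Among 14 homeostatic microglia genes 3 fell and 1 rose (6 and 1 adjusted over the list alone), with the phagocytic receptors Mertk at -2.16 ± 0.24 and Trem2 at -1.13 ± 0.19. That list had adjusted p = 0.031, adjusted p = 0.104 with an estimated correlation, and 0.092 (NC control 1). Of 21 integrated stress and ER stress genes 8 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.000514, adjusted p = 0.179 with an estimated correlation), among them Sdf2l1 (1.77 ± 0.19). In cholesterol synthesis and uptake 7 of 19 rose (7 adjusted over the list alone, adjusted p = 0.000525, adjusted p = 0.11 with an estimated correlation). In glycolysis and hypoxia 6 of 19 fell (7 down and 1 up adjusted over the list alone). In the Bcl2 family 3 of 12 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted p = 0.121), with the survival factor Bcl2l1 at 0.92 ± 0.18 and the BH3-only Bmf at -1.54 ± 0.27. The necroptosis pathway had 3 of 14 up (3 up and 1 down adjusted over the list alone, adjusted p = 0.181). No apoptosis execution gene of 13 passed (0 adjusted over the list alone, adjusted p = 0.854).

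In all, 1958 genes passed at 12 h in the NC line, 1070 higher and 888 lower, and 1057 of them changed at least 2-fold. With the replicate number as a block the count was 3948, and Mcl1 passed as well (0.32, adjusted p = 0.00208, against 0.186). On log2(TPM + 0.1), limma's share of higher calls was 64.7% against 54.6%. DNA replication (6 of 23 down, 8 down and 1 up adjusted over the list alone), mitochondrially encoded (4 of 9 down, 8 adjusted over the list alone) and heat shock genes (3 of 9 up, 5 adjusted over the list alone) passed at adjusted p = 0.00177, 9.45e-05 and 0.0137 with camera, and had adjusted p = 0.216, 0.216 and 0.156 with an estimated correlation. The glycolysis, ferroptosis (3 of 17 up, 3 adjusted over the list alone) and neuron marker lists (1 of 2 down, 1 adjusted over the list alone) lay at the threshold, with adjusted p = 0.0498, 0.0497 and 0.0482, and adjusted p = 0.325, 0.195 and 0.145 with an estimated correlation. They lost the call in 14, 13 and 13 of the 18 fits without 1 library (adjusted p up to 0.139, 0.166 and 0.092), the first and second also with RLE factors (0.05 each) and the third with the block (0.0799). The p53 list (3 of 13 up, 4 adjusted over the list alone, adjusted p = 0.0613) passed with the block (0.0487) and in some fits without 1 library, at 0.0386 (NC 12 h 2), 0.0394 (NC control 1). Lists not past the threshold were the inflammasome (2 of 11 up, 2 adjusted over the list alone, adjusted p = 0.12, 0.0461 (NC control 2)), nuclear oxidative phosphorylation (0 of 23, 0 adjusted over the list alone, adjusted p = 0.746) and disease-associated microglia (1 of 17 up and 1 down, 1 and 2 adjusted over the list alone, adjusted p = 0.965). Nor did alternative activation (3 of 7 up and 3 down, 3 and 3 adjusted over the list alone, adjusted p = 0.899) and lysosome genes (3 of 20 up and 2 down, 4 and 2 adjusted over the list alone, adjusted p = 0.557) pass. The same held for antigen presentation (2 of 12 up, 2 adjusted over the list alone, adjusted p = 0.38), immediate early genes (4 of 15 up and 3 down, 7 and 3 adjusted over the list alone, adjusted p = 0.173, 0.0444 (NC 12 h 2)) and ribosomal proteins (1 of 24 up, 1 adjusted over the list alone, adjusted p = 0.903). For the disease-associated microglia, alternative activation and ribosomal lists, median, mean and test differed in sign. Few markers of other cells were detected. They were Alas2 and Bpgm of erythroid cells (0 of 2, 0 adjusted over the list alone, adjusted p = 0.67), S100b and Aldoc of astrocytes (0 of 2, 1 up adjusted over the list alone, adjusted p = 0.854), and Pecam1 and Kdr of fibroblasts and endothelium (1 of 2 up, 1 adjusted over the list alone, adjusted p = 0.0799, 0.0499 (NC 12 h 1), 0.0483 (NC control 3)). The globin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt had 0 counts.

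After 24 h of oxyhemoglobin, the second time the study sampled, the NC line had high cytokine transcripts while its interferon genes lay under the control level. Csf3 was up by 8.68 ± 0.42, Ccl7 by 5.79 ± 0.22, Il1a by 5.83 ± 0.31, Il1b by 5.58 ± 0.37, Il6 by 4.06 ± 0.36, Tnf by 3.14 ± 0.37, Nos2 by 3.01 ± 0.29 and Ptgs2 by 2.81 ± 0.18 over control. The interleukin-36 family member Il1f9 was at least 54-fold higher and Gm14275 at least 28.6-fold higher than in controls without a count. The leukotriene receptor Ltb4r1 rose from 1 to 154 counts over the groups, a ratio of count rates of 165 with an exact 95% interval of 29.2 to 6560. Of 18 inflammatory genes 16 rose and 1 fell (16 and 1 adjusted over the list alone, camera adjusted p = 4.95e-31), and of 14 NF-kB targets 6 rose (7 adjusted over the list alone, adjusted p = 2.54e-05). Of 26 interferon response genes 10 fell and none rose (16 down adjusted over the list alone, adjusted p = 4.46e-12), among them the oligoadenylate synthetase Oas2 (-2.14 ± 0.33) and Oasl2 (-1.67 ± 0.21). Homeostatic microglia genes fell in 6 of 14 (6 adjusted over the list alone, adjusted p = 0.000464), with the complement subunit C1qc at -3.33 ± 0.59 and Trem2 at -1.02 ± 0.19. Of the disease-associated microglia genes 3 of 17 fell (4 adjusted over the list alone), with Igf1 at -1.70 ± 0.26, Apoe at -1.58 ± 0.27 and Lgals3 at -1.12 ± 0.24, and the list did not pass (adjusted p = 0.204, 0.0207 (NC 24 h 3)). NRF2 targets rose in 9 of 19 (11 up and 1 down adjusted over the list alone, adjusted p = 1.05e-08), with Slc7a11 at 2.36 ± 0.22. In heme and iron handling 8 of 19 rose (10 adjusted over the list alone, adjusted p = 0.000142, adjusted p = 0.104 with an estimated correlation), with Hmox1 at 2.15 ± 0.27. Cholesterol genes rose in 3 of 19 (4 adjusted over the list alone, adjusted p = 0.00118, adjusted p = 0.136 with an estimated correlation), and glycolysis and hypoxia genes fell in 6 of 19 (7 adjusted over the list alone, adjusted p = 0.0021, adjusted p = 0.186 with an estimated correlation). No G2/M gene of 20 and no necroptosis gene of 14 passed (0 of each adjusted over the list alone, adjusted p = 0.745 and 0.745). In all 1211 genes passed, 745 higher and 466 lower. The count was 3023 with the replicate block, 748 with only the compared groups fitted and 802 without the libraries numbered 2. Limma on log2(TPM + 1) put 42.7% of its calls on the higher side, against 61.5%. Bcl2 (0.31 ± 0.15, adjusted p = 0.273) passed with the block (0.31, adjusted p = 0.0211). Lists gained without 1 library were mitochondrially encoded, 0.00036 (NC 24 h 1), DNA replication, 0.0463 (NC 24 h 2), heat shock, 0.0456 (NC control 1), immediate early, 0.0463 (NC 24 h 2), fibroblast and endothelium, 0.0443 (NC 12 h 1), 0.0302 (NC control 3), and neuron, 0.0436 (NC 12 h 3), 0.0483 (NC control 2). For the Bcl2 family and G2/M lists, median, mean and test differed in sign.

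What changed between 12 h and 24 h in the NC line was tested directly. Interferon genes fell and cell division genes rose. The guanylate-binding protein Gbp2 fell (-5.98 ± 0.46), as did Isg15 (-2.49 ± 0.19), and 18 of 26 interferon response genes fell (25 adjusted over the list alone, camera adjusted p = 8.4e-43). The collagenase Mmp13 fell (-3.78 ± 0.23), and Il1b, Il1a and Ccl5 changed by -2.27 ± 0.25, -1.55 ± 0.23 and -1.49 ± 0.27. Of 18 inflammatory genes 6 fell (9 down and 1 up adjusted over the list alone, adjusted p = 1.76e-06), and of 14 NF-kB targets 1 fell (5 adjusted over the list alone, adjusted p = 0.000198). G2/M and mitosis genes rose in 9 of 20 (15 adjusted over the list alone, adjusted p = 2.32e-16), with Top2a at 1.15 ± 0.15. DNA replication genes rose in 8 of 23 (13 adjusted over the list alone, adjusted p = 1.88e-10). Mitochondrially encoded genes, whose reads nuclear copies may share, rose in 8 of 9 (9 adjusted over the list alone, adjusted p = 9.75e-12, adjusted p = 0.0735 with an estimated correlation). Integrated stress and ER stress genes fell in 5 of 21 (10 adjusted over the list alone, adjusted p = 2.12e-06, adjusted p = 0.0883 with an estimated correlation). The NRF2, disease-associated microglia, lysosome and antigen presentation lists were lower with 1, 1, 0 and 0 members past the threshold (1, 1, 0 and 0 adjusted over the list alone). Their adjusted p were 0.00783, 0.0281, 0.00589 and 0.0216, and adjusted p = 0.284 for the first and 0.336 for the others with an estimated correlation. The NRF2 call was lost at 0.0566 (NC 12 h 3), 0.0526 (NC 24 h 1), 0.0528 (NC 24 h 2). The disease-associated microglia call was lost at 0.136 (NC 12 h 1), 0.0712 (NC 12 h 3), 0.129 (NC 24 h 1), 0.136 (NC 24 h 2). The lysosome call was lost at 0.0538 (NC 12 h 3), 0.0633 (NC 24 h 2). The antigen presentation call was lost at 0.0565 (NC 12 h 1), 0.0712 (NC 12 h 3), 0.167 (NC 24 h 2). In all 441 genes passed, 261 higher and 180 lower, and 1841 passed with the replicate block, 46.8% of them higher. The count was 209 without NC 12 h library 1, 195 without NC 12 h library 3, 231 without NC 24 h library 2 and 287 without NC 24 h library 3. It was 263 with only these groups fitted and 276 without the libraries numbered 2. The share of higher calls was 59.2% and turned to 16.1% with limma on log2(TPM + 1), a scale on which the median of all genes moved by -0.13. With the block the alternative activation list passed (adjusted p = 0.0279 against 0.127, 0.022 (NC 12 h 2), 0.0492 (NC 24 h 1), 0.0484 (NC 24 h 3)), as did Mcl1 (-0.33, adjusted p = 0.0042) and Nos2 (0.87, adjusted p = 0.0491). Gained without 1 library were the Bcl2 family, 0.0493 (KD control 1), 0.0301 (NC 12 h 2), ribosomal, 0.013 (NC 12 h 2), ferroptosis, 0.0394 (NC 12 h 2), and oxidative phosphorylation, 0.0407 (NC 12 h 2). For apoptosis execution, median, mean and test differed in sign.

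The KD-labelled line was taken through the same treatment, and at 12 h cytokines were again among the largest rises. Csf3 rose by 9.69 ± 0.44, Il1a by 7.97 ± 0.34, Il1b by 7.69 ± 0.37, Ccl7 by 7.18 ± 0.24, Ptgs2 by 3.94 ± 0.19, Ccl2 by 3.05 ± 0.30, Tnf by 2.49 ± 0.38 and Nos2 by 1.69 ± 0.28. Il6 rose from 2 to 281 counts over the groups, a ratio of count rates of 152 with an exact 95% interval of 41.8 to 1260. Gm6093 and AC147806.2 were at least 38-fold and at least 37.2-fold higher than in KD-labelled controls without a count. Inflammatory genes rose in 16 of 18 and fell in 1 (16 and 1 adjusted over the list alone, camera adjusted p = 1.72e-24), and NF-kB targets rose in 10 of 14 (10 adjusted over the list alone, adjusted p = 3.72e-08). All 20 G2/M and mitosis genes fell (20 adjusted over the list alone, adjusted p = 1.12e-18), among them the mitotic kinesin Kif11 (-1.80 ± 0.15) and Top2a (-1.77 ± 0.15). Of 23 DNA replication genes 13 fell (19 adjusted over the list alone, adjusted p = 1.88e-10). Integrated stress and ER stress genes rose in 14 of 21 and fell in 1 (17 and 1 adjusted over the list alone, adjusted p = 3.18e-09), among them the pseudokinase Trib3 (2.26 ± 0.25) and the glutathione-degrading Chac1 (2.07 ± 0.24). NRF2 targets rose in 13 of 19 (14 up and 1 down adjusted over the list alone, adjusted p = 1.88e-10). Ferroptosis genes rose in 5 of 17 (5 up and 1 down adjusted over the list alone, adjusted p = 0.00218), and heme and iron genes in 9 of 19 with 1 lower (9 and 1 adjusted over the list alone, adjusted p = 0.00597, adjusted p = 0.228 with an estimated correlation). Homeostatic microglia genes fell in 8 of 14 and rose in 1 (8 and 1 adjusted over the list alone, adjusted p = 0.000427), with the purinergic receptor P2ry13 at -2.99 ± 0.37, Mertk at -3.02 ± 0.24 and C1qc at -2.21 ± 0.29. Interferon genes rose in 4 of 26 and fell in 4 (6 and 4 adjusted over the list alone, adjusted p = 0.974), Gbp2 by 3.88 ± 0.39 and Ifit2 by -0.90 ± 0.18. Bcl2l1 rose by 1.35 ± 0.18, Bmf changed by -2.02 ± 0.28, and the cytochrome c gene Cycs rose by 1.20 ± 0.26. The mitochondrially encoded list (4 of 9 down, 6 adjusted over the list alone), the cholesterol list (4 of 19 up, 5 adjusted over the list alone) and the p53 list (3 of 13 up and 1 down, 3 and 1 adjusted over the list alone) passed at adjusted p = 0.0037, 0.0378 and 0.00646. With an estimated correlation they had adjusted p = 0.467, 0.355 and 0.0813, and the first was lost at 0.0561 (KD control 2) and the second at 0.0624 (KD 12 h 1), 0.155 (KD 12 h 3), 0.0551 (KD control 1), 0.087 (KD control 2). In all 2558 genes passed, 1269 higher and 1289 lower, and 4600 with the replicate block. Higher calls were 49.6%, 52.6% with the block and 63.3% with limma on log2(TPM + 1), where the median of all genes moved by 0.107. For the interferon, inflammasome, glycolysis, alternative activation and ribosomal lists, median, mean and test differed in sign, none of which passed.

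At 24 h the KD-labelled line had high cytokine levels, and homeostatic and interferon transcripts fell against control. Csf3 was up by 8.76 ± 0.43, Ccl7 by 6.74 ± 0.23, Il1b by 4.56 ± 0.37, Ptgs2 by 3.26 ± 0.18, Nos2 by 2.61 ± 0.29 and Tnf by 2.71 ± 0.38. Il6 rose from 2 to 132 counts, a ratio of 72.1 with an exact 95% interval of 19.6 to 602. AC147806.2 and Il1f9 were at least 55-fold and 29.5-fold higher than in controls without a count. The complement gene C1qa was at least 33.9-fold lower, and C1qc (-4.66 ± 0.35), C1qb (-3.84 ± 0.35) and the mannose receptor Mrc1 (-3.88 ± 0.44) fell too. Homeostatic microglia genes fell in 8 of 14 (10 down and 2 up adjusted over the list alone, camera adjusted p = 2.3e-08). Interferon response genes fell in 17 of 26 (22 adjusted over the list alone, adjusted p = 5.88e-16), with Oasl2 at -1.75 ± 0.20. Inflammatory genes rose in 14 of 18 and fell in 1 (15 and 1 adjusted over the list alone, adjusted p = 4.11e-26), NF-kB targets rose in 6 of 14 (7 adjusted over the list alone, adjusted p = 4.49e-05) and NRF2 targets in 10 of 19 (11 adjusted over the list alone, adjusted p = 3.48e-09). Of the immediate early genes 7 of 15 rose (7 adjusted over the list alone, adjusted p = 0.000178, adjusted p = 0.3 with an estimated correlation), with the AP-1 subunit Fosl1 at 3.96 ± 0.50. Ferroptosis (5 of 17 up, 6 adjusted over the list alone), heme and iron (7 of 19 up and 1 down, 7 and 1 adjusted over the list alone), integrated stress (3 of 21 up and 1 down, 4 and 1 adjusted over the list alone) and cholesterol genes (4 of 19 up, 5 adjusted over the list alone) passed at adjusted p = 0.00138, 0.01, 0.0224 and 0.00821. With an estimated correlation they had adjusted p = 0.05, 0.261, 0.378 and 0.211. G2/M (1 of 20 down, 1 adjusted over the list alone) and p53 genes (2 of 13 up, 4 up and 1 down adjusted over the list alone) passed at adjusted p = 0.043 and 0.0124, with adjusted p = 0.211 and 0.137 with an estimated correlation. The G2/M call was lost at 0.0918 (KD 24 h 2), 0.0829 (KD 24 h 3), 0.0568 (KD control 1), 0.101 (KD control 2). The integrated stress call was lost at 0.0824 (KD 24 h 1), 0.12 (KD control 2). The p53 call was lost at 0.0513 (KD control 2). In all 1534 genes passed, 880 higher and 654 lower, and 3433 with the replicate block, where Bcl2 passed as well (0.37, adjusted p = 0.00396, against 0.136). Limma called 1012 genes on log2(TPM + 0.1) and 1019 on log2(TPM + 1) without a TPM filter, with 46.8% and 46.2% higher against 57.4%. For the inflammasome, glycolysis, disease-associated microglia, lysosome and astrocyte lists, median, mean and test differed in sign, none of which passed.

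From 12 h to 24 h in the KD-labelled line, cell division genes rose and interferon, NF-kB and stress genes fell. G2/M and mitosis genes rose in 16 of 20 (20 adjusted over the list alone, camera adjusted p = 3.84e-26), with Bub1 at 1.51 ± 0.20, and DNA replication genes in 11 of 23 (16 adjusted over the list alone, adjusted p = 1.68e-16). Gbp2 (-5.49 ± 0.46), Mmp13 (-3.81 ± 0.23), Il1b (-3.12 ± 0.26), and Il1a (-2.45 ± 0.24) fell. Interferon response genes fell in 14 of 26 (20 down and 1 up adjusted over the list alone, adjusted p = 3.62e-21), NF-kB targets in 4 of 14 (4 adjusted over the list alone, adjusted p = 0.000613) and integrated stress genes in 9 of 21 (12 adjusted over the list alone, adjusted p = 1.54e-09), with Ddit3, the CHOP transcription factor, at -1.11 ± 0.19. Inflammatory genes fell in 5 of 18 and rose in 1 (9 and 2 adjusted over the list alone, adjusted p = 0.000466, adjusted p = 0.0535 with an estimated correlation). Homeostatic genes fell in 2 of 14 (3 down and 1 up adjusted over the list alone, adjusted p = 0.0197, adjusted p = 0.0549 with an estimated correlation), with C1qc at -2.45 ± 0.36. Mitochondrially encoded (3 of 9 up, 8 adjusted over the list alone) and immediate early genes (2 of 15 up, 5 adjusted over the list alone) were higher at adjusted p = 5.12e-06 and 0.0335, with adjusted p = 0.245 and 0.53 with an estimated correlation. The necroptosis (1 of 14 down, 1 adjusted over the list alone), NRF2 (2 of 19 down, 2 adjusted over the list alone) and antigen presentation lists (0 of 12, 0 adjusted over the list alone) were lower at adjusted p = 0.0392, 0.0197 and 0.0197, and had adjusted p = 0.245, 0.315 and 0.315 with an estimated correlation. The necroptosis call was lost at 0.136 (KD 12 h 1), 0.0904 (KD 12 h 3), 0.0514 (KD 24 h 1), 0.144 (KD 24 h 2). The NRF2 call was lost at 0.0984 (KD 12 h 1), 0.0808 (KD 24 h 2). The antigen presentation call was lost at 0.0535 (KD 12 h 1), 0.104 (KD 12 h 3), 0.274 (KD 24 h 2). The homeostatic call was lost at 0.0508 (KD 12 h 1), 0.051 (KD 24 h 2). The immediate early call was lost at 0.151 (KD 12 h 2). In all 684 genes passed, 450 higher and 234 lower, and 1971 with the replicate block, where the lysosome list (adjusted p = 0.0327 against 0.066, 0.0214 (KD 12 h 2), 0.0435 (KD 24 h 1), 0.027 (KD 24 h 3)) and Bcl2l1 (-0.39, adjusted p = 0.0423) passed too. The count was 449 without KD 12 h library 2, 428 without KD 24 h library 1 and 433 without the libraries numbered 2. Higher calls were 65.8%, and 33.9% with limma on log2(TPM + 1), where the median of all genes moved by -0.183. The Bcl2 family passed without 1 library at 0.0214 (KD 12 h 2), 0.0477 (KD 24 h 3). For the heme, heat shock and ribosomal lists, median, mean and test differed in sign.

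**Figure D2:**
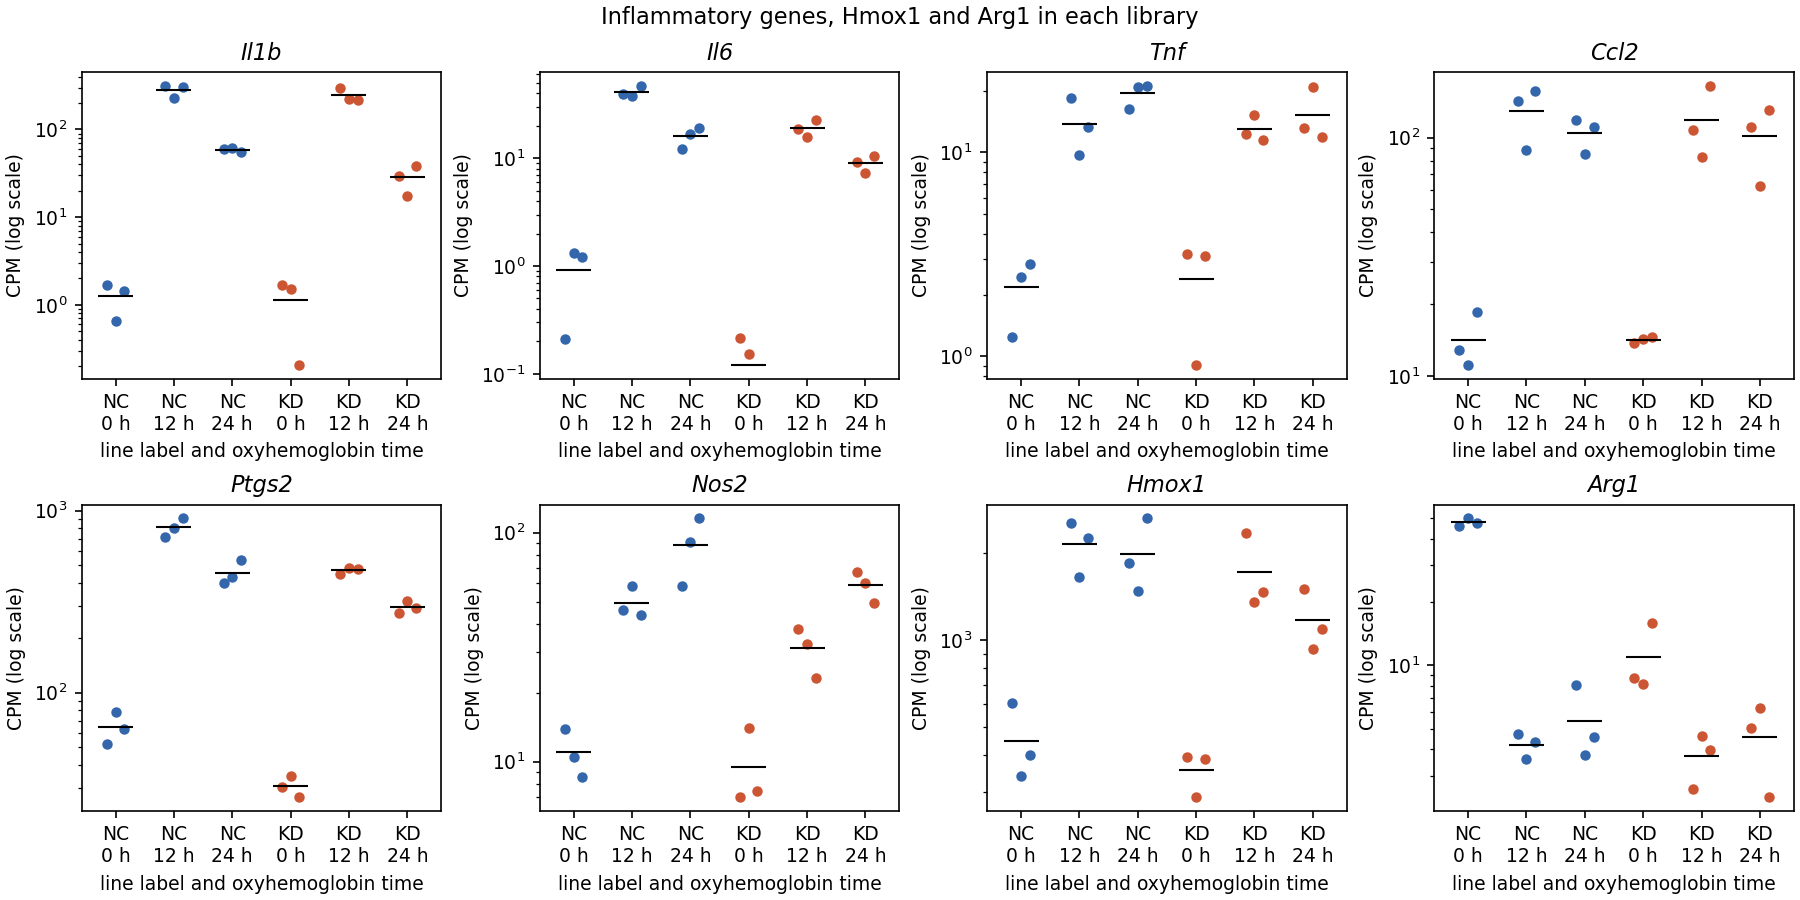
CPM on a log scale (vertical axes) of Il1b, Il6, Tnf, Ccl2, Ptgs2, Nos2, Hmox1 and Arg1 in the 18 libraries, by line label and time (horizontal axes), with points for libraries and bars for group means. Libraries at 0 counts enter the means but have no point on the log axes. In both lines the first 7 genes lie higher and Arg1 lower at 12 h and 24 h than at control.

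**Figure D3:**
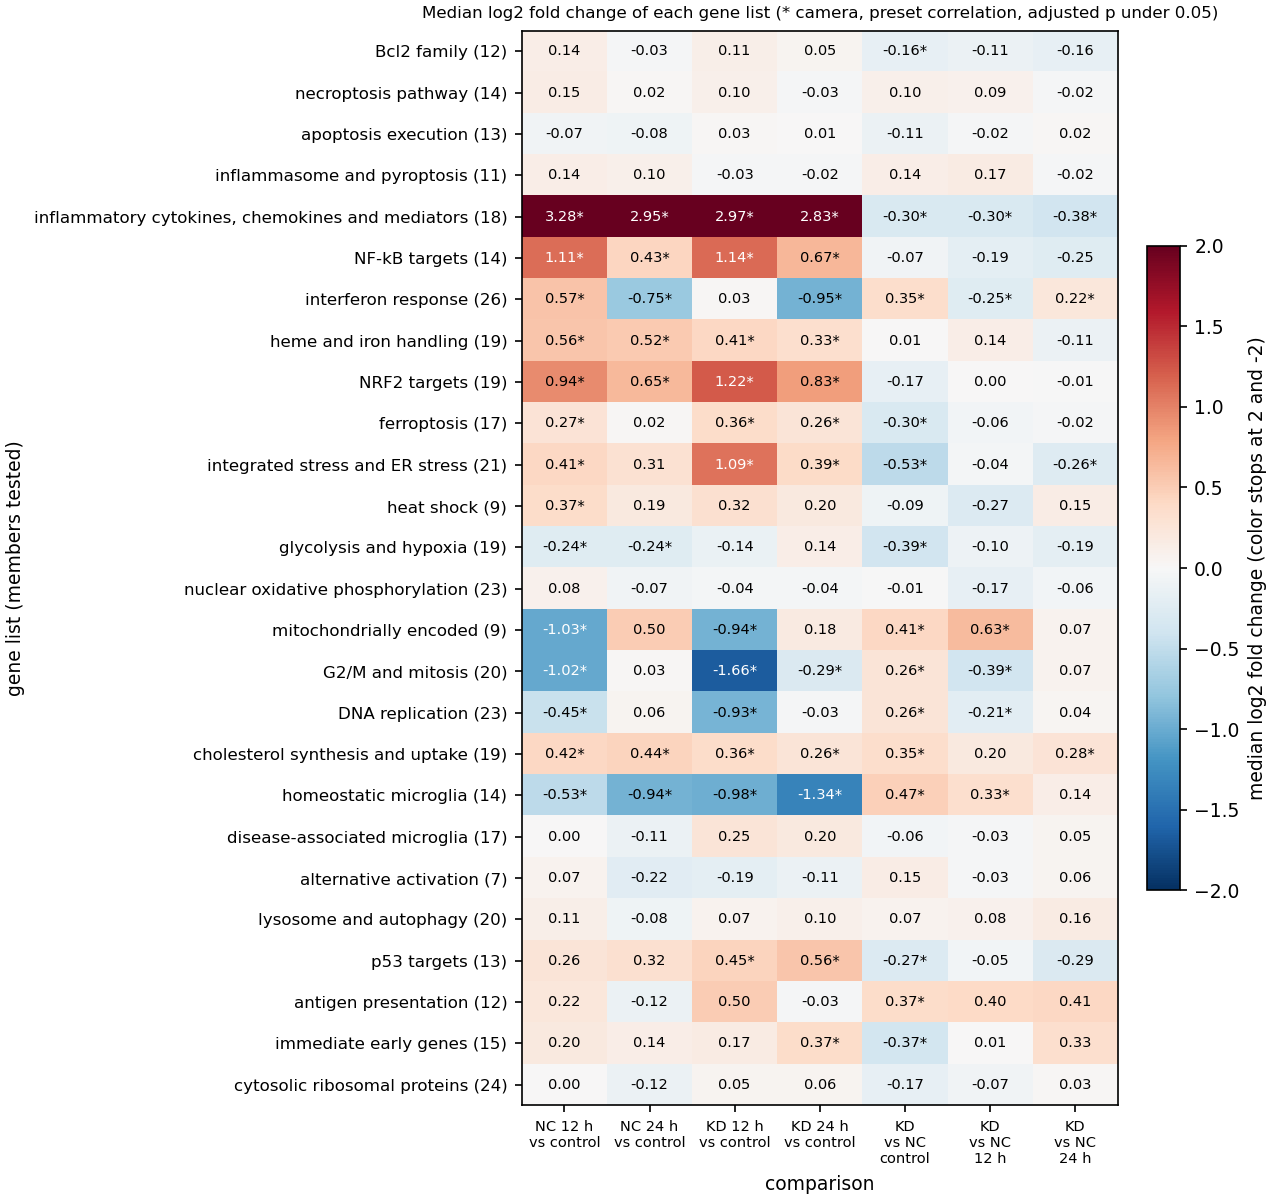
Median log2 fold change (color, stopping at 2 and -2) of each gene list (vertical axis, with the number of members tested) in 7 comparisons (horizontal axis), without the markers of other cell types. Stars mark lists past an adjusted p of 0.05 in camera with the preset correlation of 0.01.

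How alike the 2 lines responded was asked across genes, with no library shared between the lines. Over 15996 genes the 12 h responses correlated with Pearson r = 0.725 and Spearman rho = 0.625, and the 24 h responses with 0.67 and 0.546. Genes are not independent replicates, and these values describe the 18 libraries. Among genes with at least 5 CPM in 3 libraries r was 0.812 and 0.769. At 12 h, 762 genes rose in both lines where 84.9 would overlap in independent lists, 666 fell in both where 71.6 would, and 0 genes rose in the NC line and fell in the KD-labelled line, while 5 did the opposite. At 24 h the shared calls were 492 higher and 300 lower, against 41 and 19.1, and 0 and 1 genes were called in opposite directions.

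**Figure D4:**
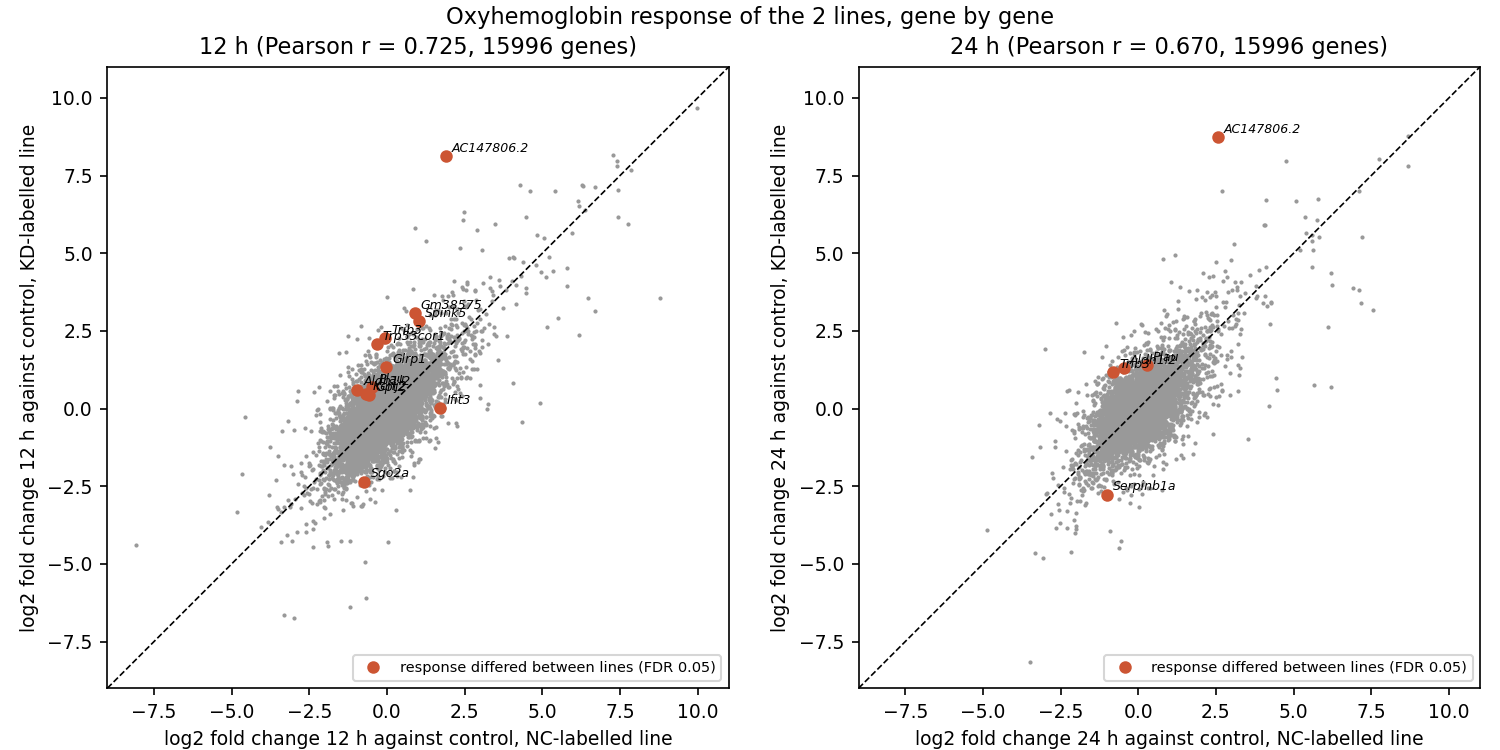
Log2 fold change against control in the NC line (horizontal axis) and in the KD-labelled line (vertical axis), 1 point per gene, at 12 h and 24 h. Colored points are genes whose response differed between the lines in the interaction test, 12 at 12 h and 5 at 24 h.

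Before treatment, the 2 lines were compared to see what separated them without oxyhemoglobin, and the complement genes stood out. In the libraries labelled KD, C1qc was higher than in NC by 4.07 ± 0.33, C1qb by 3.34 ± 0.33 and C1qa by 4.67 ± 0.77, together the subunits of the complement starter C1q. The neurofilament Nefh was higher by 3.41 ± 0.29 and the elastase Mmp12 by 3.20 ± 0.28. The orphan receptor Gpr141 had 1 count in the libraries labelled KD against 96 in NC, a ratio of 97.8 with an exact 95% interval of 17.1 to 3900. Lower too were the kinase Pkdcc at -4.91 ± 0.42, the matrix protein Thbs1 at -2.99 ± 0.26 and the protocadherin Pcdhb16, which has close paralogs and is uncertain, at -2.92 ± 0.40. Homeostatic microglia genes rose in 4 of 14 (5 adjusted over the list alone, camera adjusted p = 5.22e-10), Mertk by 1.10 ± 0.21, and interferon response genes in 3 of 26 (5 adjusted over the list alone, adjusted p = 3.16e-06), with Ifit1 at 1.36 ± 0.20. Integrated stress and ER stress genes fell in 8 of 21 (9 down and 2 up adjusted over the list alone, adjusted p = 0.000135, adjusted p = 0.142 with an estimated correlation), with Trib3 at -2.62 ± 0.25 and Chac1 at -1.83 ± 0.24. In glycolysis and hypoxia 4 of 19 fell (7 adjusted over the list alone, adjusted p = 1.59e-05, adjusted p = 0.107 with an estimated correlation). In the inflammatory list 3 of 18 fell (4 down and 1 up adjusted over the list alone, adjusted p = 0.00548, adjusted p = 0.142 with an estimated correlation), Ptgs2 at -1.08 ± 0.17 and Ccl7 at -1.14 ± 0.20. Ferroptosis genes fell in 3 of 17 (4 adjusted over the list alone, adjusted p = 0.00163, adjusted p = 0.107 with an estimated correlation), p53 targets in 2 of 13 (3 adjusted over the list alone, adjusted p = 0.0247, adjusted p = 0.142 with an estimated correlation), and immediate early genes in 2 of 15 (4 adjusted over the list alone, adjusted p = 0.0117, adjusted p = 0.463 with an estimated correlation), with Fos at -2.08 ± 0.23. Also past the preset test were DNA replication (3 of 23 up, 4 adjusted over the list alone, adjusted p = 0.00113), cholesterol (2 of 19 up, 4 adjusted over the list alone, adjusted p = 0.00101), G2/M (0 of 20, 0 adjusted over the list alone, higher, adjusted p = 0.0199), mitochondrially encoded (0 of 9, 0 adjusted over the list alone, higher, adjusted p = 0.0252), antigen presentation (0 of 12, 1 up adjusted over the list alone, higher, adjusted p = 0.046), the Bcl2 family (1 of 12 down, 2 adjusted over the list alone, adjusted p = 0.046) and fibroblast and endothelial markers (0 of 2, 1 up adjusted over the list alone, higher, adjusted p = 0.042). With an estimated correlation they had adjusted p = 0.232, 0.142, 0.142, 0.542, 0.429, 0.228 and 0.142. The Bcl2, antigen presentation and fibroblast calls were lost in 11, 9 and 5 of the 18 fits without 1 library (adjusted p up to 0.275, 0.255 and 0.169). The G2/M call was lost at 0.0591 (KD control 2), 0.0991 (NC control 3). The mitochondrially encoded call was lost at 0.542 (KD control 2), 0.0976 (NC control 1), 0.154 (NC control 3). The immediate early call was lost at 0.131 (KD control 2), 0.213 (NC control 1). The p53 call was lost at 0.105 (KD control 2), 0.109 (NC control 1). The ribosomal list passed without 1 library at 0.024 (KD control 3). For the heme, disease-associated microglia and alternative activation lists, median, mean and test differed in sign. Arg1 was lower at -2.13 ± 0.30. In all 330 genes passed, 122 higher and 208 lower in the libraries labelled KD. The count was 216 without NC control library 3, 214 without KD control library 1 and 213 without KD control library 3. Higher calls were 37%, and 51% with limma on log2(TPM + 1).

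The lines were compared again after 12 h of oxyhemoglobin, and complement genes were again among those that differed. C1qc was higher in the libraries labelled KD by 3.17 ± 0.39 and C1qb by 2.52 ± 0.37, 2 of 14 homeostatic microglia genes that passed (3 adjusted over the list alone, camera adjusted p = 0.000558). The glutathione transferase Gstm2 was higher by 3.82 ± 0.63 and Nefh by 2.62 ± 0.30. Pcdhb17 and Pcdhb16, uncertain because of close paralogs, were at -3.87 ± 0.57 and -2.77 ± 0.41, Pkdcc at -3.05 ± 0.37 and Fos at -2.37 ± 0.23. G2/M and mitosis genes were lower with 1 of 20 past the threshold (3 adjusted over the list alone, adjusted p = 0.000519), and DNA replication genes with 1 of 23 (2 adjusted over the list alone, adjusted p = 0.0289, adjusted p = 0.591 with an estimated correlation). Of 26 interferon response genes 2 fell (6 adjusted over the list alone, adjusted p = 0.00475, adjusted p = 0.157 with an estimated correlation), among them Isg15 at -1.16 ± 0.18, and of 18 inflammatory genes 2 fell (5 adjusted over the list alone, adjusted p = 0.00109, adjusted p = 0.117 with an estimated correlation). Mitochondrially encoded genes (0 of 9, 0 adjusted over the list alone) and neuron markers (1 of 2 up, Tubb3, 1 adjusted over the list alone) were higher at adjusted p = 0.00109 and 0.0362, with adjusted p = 0.581 and 0.157 with an estimated correlation. The DNA replication call was lost at 0.291 (KD 12 h 2), 0.0534 (NC 12 h 1), 0.212 (NC 12 h 3). The neuron marker call was lost at 0.079 (KD 12 h 1), 0.061 (KD 12 h 3), 0.0557 (NC 12 h 2), 0.16 (NC 12 h 3), 0.0507 (NC control 1). The Bcl2 family (1 of 12 down, 2 adjusted over the list alone), necroptosis (0 of 14, 0 adjusted over the list alone) and apoptosis execution lists (0 of 13, 0 adjusted over the list alone) did not pass (adjusted p = 0.302, 0.673 and 0.992). In all 256 genes passed, 80 higher and 176 lower, and 1737 with the replicate block. The block also brought Mcl1 (-0.50, adjusted p = 2.6e-05) and the glycolysis (adjusted p = 0.0459 against 0.195), cholesterol (0.0338 against 0.0757) and antigen presentation lists (0.00917 against 0.0757) past the threshold. Without 1 library, antigen presentation passed at 0.0126 (KD 12 h 2), 0.05 (NC 12 h 3), cholesterol at 0.0125 (KD 12 h 2), 0.05 (NC 12 h 3), ribosomal proteins at 0.00843 (KD 12 h 3), 0.00833 (NC 12 h 2) and immediate early genes at 0.0242 (KD 12 h 1), 0.00845 (NC 12 h 2). For the NRF2, disease-associated microglia, alternative activation, immediate early and erythroid lists, median, mean and test differed in sign. The count was 102 without NC 12 h library 1, 101 without NC 12 h library 3, and 166, 109 and 119 without KD 12 h libraries 1, 2 and 3. Higher calls were 31.2%, and 56.6% with limma on log2(TPM + 1), where the median of all genes moved by 0.115.

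The last comparison of the lines at a single time was at 24 h of oxyhemoglobin. The kinase Prkg2 was higher in the libraries labelled KD by 4.16 ± 0.52 and Nefh by 2.84 ± 0.28. The serpin Serpinb1a, an inhibitor of neutrophil proteases, was at -3.45 ± 0.22, Pkdcc at -4.26 ± 0.44, Pcdhb16 at -3.07 ± 0.43 and Fos at -1.41 ± 0.22. The inflammatory list was lower (3 of 18 down, 5 adjusted over the list alone, camera adjusted p = 0.0244), as was the integrated stress list (0 of 21, 2 down adjusted over the list alone, adjusted p = 0.0272), and the cholesterol (1 of 19 up, 1 adjusted over the list alone, adjusted p = 0.0231) and interferon lists (0 of 26, 2 up and 1 down adjusted over the list alone, adjusted p = 0.0393) were higher. With an estimated correlation they had adjusted p = 0.39, 0.537, 0.39 and 0.39. The inflammatory call was lost at 0.0711 (KD 24 h 2), 0.121 (NC 24 h 3). The integrated stress call was lost at 0.128 (KD 24 h 2), 0.117 (NC 24 h 1), 0.122 (NC 24 h 3). The cholesterol call was lost at 0.117 (NC 24 h 1). The interferon call was lost at 0.0537 (KD 24 h 2), 0.168 (KD 24 h 3), 0.118 (NC 24 h 1), 0.0826 (NC 24 h 2). The homeostatic list did not pass (2 of 14 up, 3 adjusted over the list alone, adjusted p = 0.0744, 0.0336 (NC 24 h 3)), nor did the Bcl2 family (adjusted p = 0.243) or the necroptosis list (adjusted p = 0.987). Antigen presentation passed without 1 library at 0.0311 (KD 24 h 2). For the necroptosis, apoptosis, inflammasome, NRF2, oxidative phosphorylation and G2/M lists, median, mean and test differed in sign. In all 223 genes passed, 75 higher and 148 lower in the libraries labelled KD. The count was 121, 97 and 131 without NC 24 h libraries 1, 2 and 3, and 69, 90 and 41 without KD 24 h libraries 1, 2 and 3. Higher calls were 33.6%, and 71.8% with limma on log2(TPM + 1).

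The average over the 3 times asked what differed between the lines in all libraries together, which does not show a difference at each time. Across 9 libraries of each line, C1qc was higher in those labelled KD by 3.33 ± 0.26, Prkg2 by 3.17 ± 0.43, Gstm2 by 3.06 ± 0.35, Nefh by 2.96 ± 0.17 and C1qb by 2.54 ± 0.22. Pkdcc stood at -4.07 ± 0.24, Gpr141 at -3.79 ± 0.47 and Pcdhb16 at -2.92 ± 0.24. Homeostatic microglia genes rose in 3 of 14 (5 adjusted over the list alone, camera adjusted p = 2.85e-06). Inflammatory genes fell in 7 of 18 (9 down and 1 up adjusted over the list alone, adjusted p = 0.00034, adjusted p = 0.1 with an estimated correlation), among them Il6 at -1.55 ± 0.28, Il1a at -0.84 ± 0.18, Ptgs2 at -0.83 ± 0.10 and Ccl7 at -0.53 ± 0.11. Integrated stress genes fell in 6 of 21 (7 adjusted over the list alone, adjusted p = 0.00296, adjusted p = 0.327 with an estimated correlation), with Trib3, which passed at control and not at 12 h or 24 h, at -1.18 ± 0.14, and glycolysis and hypoxia genes in 5 of 19 (5 adjusted over the list alone, adjusted p = 0.00514, adjusted p = 0.327 with an estimated correlation), with the ER oxidase Ero1l at -1.26 ± 0.15. Cholesterol genes rose in 6 of 19 (7 adjusted over the list alone, adjusted p = 0.00103, adjusted p = 0.234 with an estimated correlation), with Lss at 0.70 ± 0.13. Antigen presentation (1 of 12 up and 1 down, 2 and 1 adjusted over the list alone) and mitochondrially encoded genes (0 of 9, 2 up adjusted over the list alone) were higher at adjusted p = 0.0177 and 0.0085, with adjusted p = 0.377 and 0.501 with an estimated correlation, and the first was lost at 0.0535 (KD 24 h 3), 0.0562 (NC 24 h 2), 0.0503 (NC control 2). In the Bcl2 family 3 of 12 fell (4 adjusted over the list alone, adjusted p = 0.0817, 0.0493 (KD control 3)), Bcl2l11 at -0.50 ± 0.08 and Mcl1 at -0.35 ± 0.09. The necroptosis list had no member past the threshold (0 of 14, 0 adjusted over the list alone, adjusted p = 0.648). The AP-1 subunit Fos was at -1.95 ± 0.13 and Arg1 at -0.83 ± 0.20. In all 1598 genes passed, 642 higher and 956 lower, and 57 passed at each of the 3 times singly, 19 higher and 38 lower. The NF-kB list passed without 1 library at 0.0363 (KD control 1). For the NRF2 and immediate early lists, median, mean and test differed in sign. Higher calls were 40.2%, and 65.4% with limma on log2(TPM + 1).

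**Figure D5:**
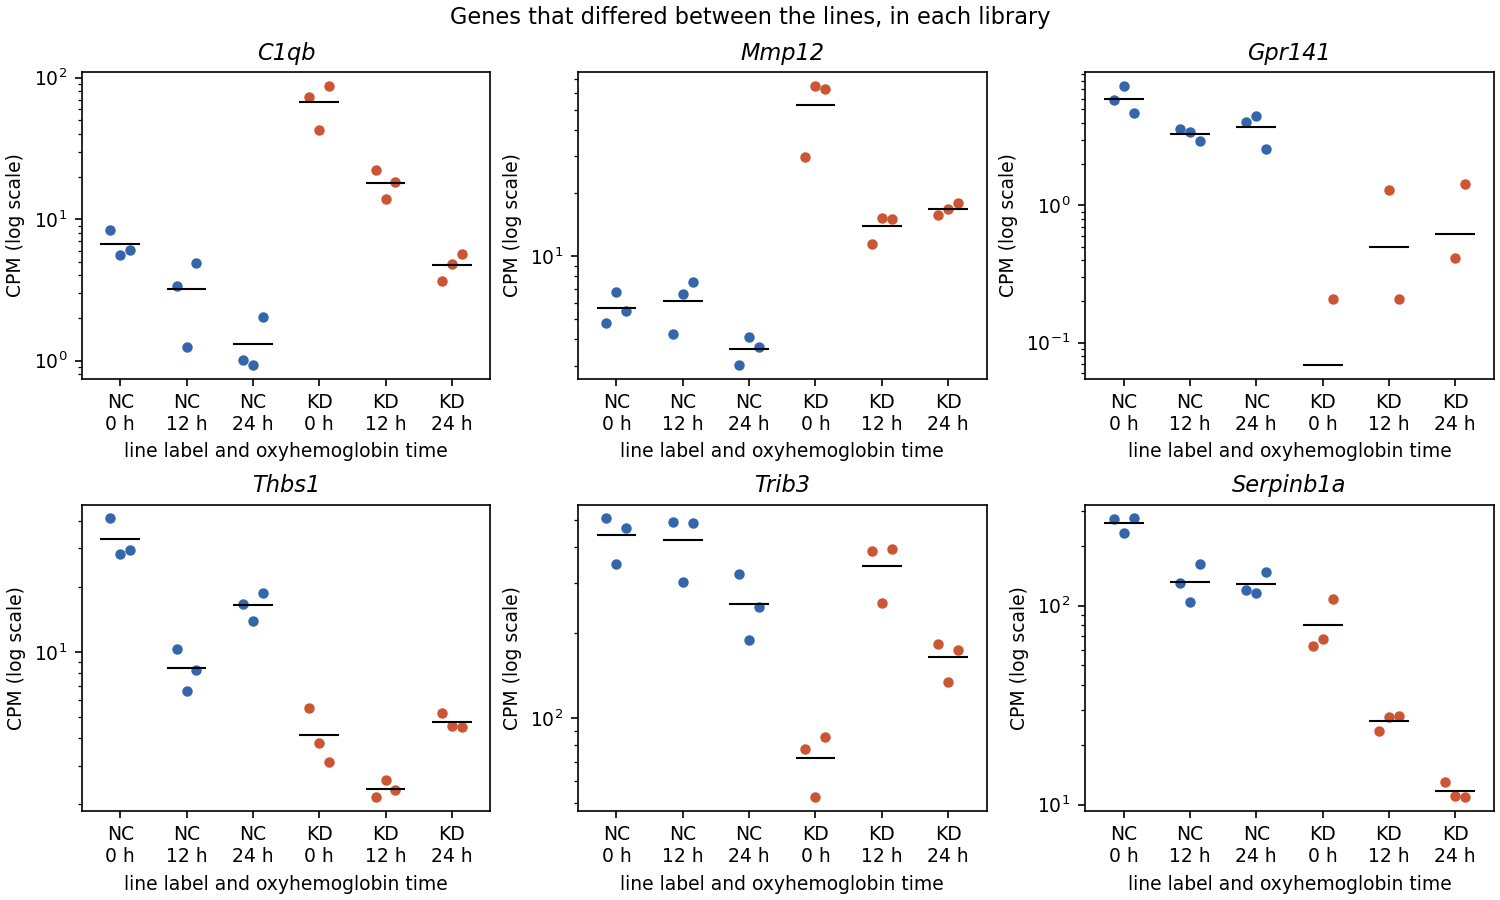
CPM on a log scale (vertical axes) of C1qb, Mmp12, Gpr141, Thbs1, Trib3 and Serpinb1a in the 18 libraries, by line label and time (horizontal axes), with points for libraries and bars for group means. Libraries at 0 counts enter the means but have no point on the log axes. C1qb and Mmp12 lie higher, and Thbs1 and Serpinb1a lower, in the libraries labelled KD.

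Whether the 12 h response differed between the lines was tested as the interaction of line and time, and 12 genes passed, 10 with a more positive response in the libraries labelled KD. Trib3, a stress-induced pseudokinase, differed by 2.31 ± 0.34. Its level was 443 ± 81.3 CPM (SD, n = 3) in NC control and 427 ± 109 at 12 h, against 72.4 ± 17.3 and 346 ± 79 in the libraries labelled KD. The mitochondrial folate enzyme Aldh1l2 differed by 1.56 ± 0.24 and passed in the 18 fits without 1 library, as did Trib3. Of the interferon response genes 1 of 26 was more negative (9 down adjusted over the list alone, camera adjusted p = 3.12e-13). G2/M genes (0 of 20, 5 down adjusted over the list alone, adjusted p = 3.08e-09), homeostatic genes (0 of 14, 0 adjusted over the list alone, adjusted p = 0.00672) and DNA replication genes (0 of 23, 7 down adjusted over the list alone, adjusted p = 1.61e-07, adjusted p = 0.121 with an estimated correlation) were also more negative. Ferroptosis (0 of 17, 2 up adjusted over the list alone), integrated stress (1 of 21 up, 4 up and 1 down adjusted over the list alone) and glycolysis genes (0 of 19, 1 up adjusted over the list alone) were more positive at adjusted p = 0.0201, 0.00513 and 0.0089, with adjusted p = 0.201, 0.327 and 0.327 with an estimated correlation. The ferroptosis call was lost at 0.0685 (KD 12 h 1), 0.0662 (KD 12 h 3), 0.0507 (KD control 2), 0.238 (NC 12 h 2), 0.102 (NC control 1). The integrated stress call was lost at 0.0879 (KD 12 h 1), 0.053 (KD control 2), 0.11 (NC 12 h 2). The glycolysis call was lost at 0.0685 (KD 12 h 1), 0.0721 (KD 12 h 3), 0.0729 (KD control 2), 0.0957 (NC 12 h 2), 0.126 (NC control 1). Il1b (-0.16 ± 0.62), Tnf (-0.13 ± 0.55) and Hmox1 (0.01 ± 0.37) did not pass. The fibroblast and endothelial list passed without 1 library at 0.0263 (KD 12 h 3), 0.0337 (KD control 3), 0.0331 (NC 12 h 1), 0.0427 (NC control 3), and p53 targets at 0.0275 (KD 12 h 2), 0.0389 (NC 12 h 1). For the necroptosis, heme, disease-associated microglia, alternative activation, lysosome, antigen presentation and ribosomal lists, median, mean and test differed in sign. Unadjusted p was under 0.05 in 904 genes, little above chance. The count was 19 and 7 without NC control libraries 1 and 2, 3 and 7 without NC 12 h libraries 1 and 3, 6, 7 and 7 without KD control libraries 1, 2 and 3, and 6 and 7 without KD 12 h libraries 2 and 3. Calls higher were 83.3%, and 64.3% with limma on log2(TPM + 1).

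At 24 h the same test called 5 genes, 4 more positive in the libraries labelled KD. Aldh1l2 differed by 1.77 ± 0.24, with 84.3 ± 3.68 CPM (SD, n = 3) in NC control and 60.9 ± 2.48 at 24 h, against 23.4 ± 5.46 and 57.6 ± 4.29 in the libraries labelled KD. Homeostatic microglia genes were more negative (0 of 14, 1 down adjusted over the list alone, camera adjusted p = 1.91e-05), as were DNA replication genes (0 of 23, 1 down adjusted over the list alone, adjusted p = 0.0272, adjusted p = 0.793 with an estimated correlation). Immediate early (0 of 15, 2 up adjusted over the list alone), ferroptosis (0 of 17, 2 up adjusted over the list alone) and glycolysis genes (0 of 19, 0 adjusted over the list alone) were more positive at adjusted p = 0.00037, 0.0028 and 0.0058, with adjusted p = 0.52, 0.142 and 0.487 with an estimated correlation. The DNA replication call was lost at 0.16 (KD 24 h 2), 0.0999 (KD control 1), 0.119 (KD control 3), 0.186 (NC 24 h 3), 0.0682 (NC control 1), 0.144 (NC control 2). The glycolysis call was lost at 0.0511 (NC 24 h 2), 0.0684 (NC control 1), the immediate early call at 0.0682 (NC control 1). G2/M genes passed without 1 library at 0.0453 (KD 24 h 1), 0.0229 (NC 24 h 1), 0.0496 (NC control 2), interferon genes at 0.0193 (KD 24 h 3), 0.0446 (KD control 2), 0.0348 (NC 24 h 1), 0.0106 (NC control 3), and mitochondrially encoded genes at 0.000968 (NC 24 h 1). For the Bcl2 family, alternative activation and antigen presentation lists, median, mean and test differed in sign. Unadjusted p was under 0.05 in 740 genes, fewer than by chance. The count was 3 and 2 without NC control libraries 1 and 3, 9 without NC 12 h library 2, 10, 3 and 3 without NC 24 h libraries 1, 2 and 3, 3 without KD control library 2, and 2 and 2 without KD 24 h libraries 1 and 3. Calls higher were 80%, and 69.2% with limma on log2(TPM + 1).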

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

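The tests of splits with equal exchange were chosen only after the first splits had been seen, and the other tests of this part were planned before their results were seen. Directions between lines follow the labels, which Bak1 did not check. Each result in this part stands here because the response to oxyhemoglobin differed between the 2 lines in the interaction test. At 12 h the difference of the responses, KD-labelled minus NC, was 6.25 for AC147806.2 (adjusted p = 0.00283, edgeR), whose KD control libraries had no count, 2.41 for Trp53cor1 (0.019), 2.31 for Trib3 (0.00578), 2.19 for Gm38575 (0.0328), 1.78 for Spink5 (0.019), 1.56 for Aldh1l2 (0.00915), 1.34 for Glrp1 (0.019), 1.16 for Plau (0.019), 1.11 for Kcnj2 (0.019), 1.01 for Gpt2 (0.0328), -1.62 for Sgo2a (0.0115) and -1.69 for Ifit3 (0.019). At 24 h it was 6.16 for AC147806.2 (0.00173), 1.99 for Trib3 (0.0252), 1.77 for Aldh1l2 (0.00173), 1.13 for Plau (0.0447) and -1.75 for Serpinb1a (0.0186). The fitted values of AC147806.2 depend on the prior count, and its bounds were 3.33 and 3.21. Glrp1, Plau, Kcnj2 and Gpt2 at 12 h lie outside the rule and were named after they were seen. These 4 lost the call at least without NC 12 h library 1 (3 genes passed). Of the 18 fits without 1 library, the call was lost at 12 h in 5 for Trp53cor1 (adjusted p up to 0.083), 10 for Gm38575 (0.201), 6 for Spink5 (0.125), 6 for Ifit3 (0.0816) and 1 for Sgo2a (0.0579, without NC 12 h library 1). At 24 h it was lost in 8 for Trib3 (0.0829), 11 for Plau (0.145) and 5 for Serpinb1a (0.0829). Trib3 lies on chromosome 2 from 152337422 to 152344032 and Aldh1l2 on chromosome 10 from 83487450 to 83534140 (GRCm38).

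Among gene lists the mean difference at 12 h was -0.73 for interferon response, 0.23 for ferroptosis, 0.45 for integrated stress and ER stress, 0.31 for glycolysis and hypoxia, -0.69 for G2/M and mitosis, -0.48 for DNA replication and -0.59 for homeostatic microglia. At 24 h it was 0.33 for ferroptosis, 0.31 for glycolysis and hypoxia, -0.23 for DNA replication, -0.80 for homeostatic microglia, which includes C1qa fitted against a group without counts, and 0.45 for immediate early genes. With an estimated correlation 3 of the 7 calls at 12 h were left (interferon, G2/M and homeostatic) and 1 of the 5 at 24 h (homeostatic), the others at adjusted p = 0.121 to 0.327 and 0.142 to 0.793. Calls lost without 1 library are named beside the results. All 7 lists at 12 h and 5 at 24 h also passed between the lines at control, in the opposite direction. A difference before treatment stays open for the lists too.

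For the gene calls, 3 explanations were weighed. The count share of CT010467.2 stays open: all 17 calls held without it, but TMM already trims such a gene. The libraries numbered 2 stay open. Without them the median ratio of differences was 0.99, all 17 kept their sign and 3 calls were left with fewer libraries. The calls were picked with those included. A difference of the lines before treatment stays open. Of 13 genes, 10 differed more at control than at the treated time (exact two-sided sign test, p = 0.0923, genes sharing libraries). Trib3, Aldh1l2 and Gpt2 started apart at control (-2.62, -1.85, -1.27) and did not pass at 12 h (-0.3, -0.29, -0.26). A different response of the lines, a biological explanation, cannot be told from that.

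Other splits of the same libraries settled the count at neither time. At 12 h 5 of 60 splits gave at least the real 12 genes, the highest of the others 844, and at 24 h 11 of 60 gave at least the real 5, the highest of the others 512. Chance was not excluded by these splits. The others that reached the counts exchanged unequal numbers of libraries between times, which lets the difference between lines in, a structure of the samples. Among 82 splits that exchanged equal numbers at both times, 2 reached the count at 12 h. The other of them called 1968 genes, which points to a structure of the samples whose cause was not found. It placed the 4 libraries numbered 2 on the same side of the interaction, but 7 of the 8 splits that did so called no gene. With the replicate block the interaction called 331 genes, 38.1% of them more positive, against 83.3%. At 24 h 1 of 82, the real one, reached the count, with 1 gene as the highest of the others. These splits were chosen for what the first had shown, so chance stays open at both times.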

How the results depend on the processing

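The groups, tests, gene lists, named-gene rule and alternatives were chosen before the data were examined, except that leaving out CT010467.2, the libraries numbered 2 together, or chromosomes 4, 9, 13 and 16 was chosen after seeing the data. No named gene past the threshold turned its direction with DESeq2, RLE factors, the block, limma on log2(TPM + 1), run for 693 of 744 named results, or without 1 library, and named genes were not followed through the other settings, while the share of higher calls moved over or under 50% with TPM in several comparisons, as given beside the results. It did so too with the block, to 46.8% for NC 24 h against 12 h, 38.1% for the 12 h interaction and 52.6% for KD 12 h, the last also with DESeq2 (51.1%) and no filter (50.7%). Of 744 named gene results 604 passed, and 447 of these passed in all 18 fits without 1 library. DESeq2 lost 2 and gained 6 named calls, RLE lost 3, the block gained 16, and TPM lost 127 of 577. Depth limits Bak1 and other genes of few counts, and 3 libraries a group limit the interactions most. Where a value moved, the cause was not tested.

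Genes past the threshold are given for comparisons moved by over 1.5 times. With the replicate block, the counts were 1496, 1737, 1440 and 3902 between the lines at control, 12 h, 24 h and on average, 3948, 3023 and 1841 for NC 12 h, 24 h and 24 h against 12 h, 4600, 3433 and 1971 for the KD-labelled line, and 331 and 193 for the interactions at 12 h and 24 h. With only the compared groups fitted they were 160, 115 and 119 between the lines by time, 748 and 263 for NC 24 h and 24 h against 12 h, and 2 for the 12 h interaction. Limma on log2(TPM + 1) gave 208, 113, 103 and 1017 between the lines and 13 for the 24 h interaction, log2(TPM + 0.1) gave 198, 103, 108 and 980, 1012 for KD 24 h and 10 for the 24 h interaction, and log2(TPM + 1) without a filter gave 123 and 119 at 12 h and 24 h, 1047 on average, 1019 for KD 24 h and 19 and 25 for the interactions. DESeq2 gave 386 between the lines at 24 h and 53 and 38 for the interactions, no filter 46 and 33, and upper-quartile factors and the stricter filter 8 each for the 24 h interaction. Without the libraries numbered 2 the counts were 157, 147 and 59 between the lines by time, 802 and 276 for NC 24 h and 24 h against 12 h, 433 for KD 24 h against 12 h and 2 and 1 for the interactions. Leaving out the 4 chromosomes gave 139 at 12 h between the lines. DESeq2 left the adjusted p of 10102 to 15710 genes as NA.

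Gene lists past the threshold with an estimated correlation were 2, 2, 0 and 1 between the lines at control, 12 h, 24 h and on average, 5, 5 and 5 for NC 12 h, 24 h and 24 h against 12 h, 5 and 5 for KD 24 h and 24 h against 12 h, and 3 and 1 for the interactions. With fry in one direction they were 14 for NC 24 h and 4 and 1 for the interactions, and with either direction 9 and 19 between the lines at 24 h and on average, 20 for NC 24 h, 21 and 20 for KD 12 h and 24 h and 3 for the 24 h interaction. With the block 2 passed between the lines at 24 h. The correlations of the responses were 0.812 and 0.769 with the stricter filter and 0.892 and 0.883 among genes past the threshold in the average response.

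Only the lines at 12 h and times within a line passed the 0.1 cut for pairs. Same-number correlations were 0.07 to 0.467 throughout, and all 18 libraries correlated best within their number. The data, not the design, hint at pairs throughout. In the other comparisons the block brought the ribosomal list at control to adjusted p = 0.0275 and the fibroblast list to 0.0868. It brought the inflammatory and interferon lists at 24 h between the lines to 0.0578 and 0.0782. It brought the interferon and G2/M lists of the 24 h interaction to 0.0177 and 0.0219. It brought past the threshold Arg1 in the interactions (1.99, adjusted p = 0.00674, and 1.96, 0.00802; with DESeq2 0.0251 and 0.0362), Bax (0.033) and Hmox1 (0.00478) on average, Il6 (0.0218) at control, and Hmox1 (0.0156), Il6 (0.00939), Mcl1 (0.00837) and Ptgs2 (2.2e-05) at 24 h between the lines. The block changed no list or named-gene call but those given here and beside the results.

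Without 1 library at a time, the Bak1 difference of 0.69 ran from 0.31 to 1.25. Genes past the threshold ran from 213 to 354, 101 to 271, 41 to 248 and 1278 to 1646 between the lines, 1331 to 2016, 838 to 1281 and 195 to 479 in the NC line, 1867 to 2673, 1086 to 1618 and 428 to 726 in the KD-labelled line, and 3 to 19 and 2 to 10 for the interactions. Lists ran from 9 to 15, 6 to 8, 1 to 4 and 6 to 8, then 12 to 15, 8 to 10 and 7 to 16, then 10 to 12, 9 to 12 and 8 to 14, and 4 to 9 and 2 to 8. The response correlations ran from 0.65 to 0.711 at 12 h and 0.606 to 0.648 at 24 h.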

Other observations

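The families and chromosomes in this part were named after the results had been seen, as were the tests of shared exons, exchanged labels, chromosome copies and removed histone genes, while the tests of other splits, of counts lost at overlapping genes, of the libraries numbered 2 and of gene length and expression were planned before their results were seen. Directions between lines follow the labels. Replication-dependent histone genes, which package newly made DNA and whose copies share reads, were counted as a family without a test of the family. Of 55 tested, 41 fell at 12 h in the NC line (median log2 change -1.12) and 51 in the KD-labelled line (median -2.03). From 12 h to 24 h, 25 rose in the NC line (median 0.87) and 46 in the KD-labelled line (median 1.55). At 24 h against control, 1 was lower in the NC line, and 7 lower and 1 higher in the KD-labelled line. At 12 h 21 were lower and 1 higher in the libraries labelled KD than in NC (median -0.88), against 0 called at control (median -0.03). The interaction at 12 h called 0 of them with edgeR (median -0.84), so a difference between the responses was not shown gene by gene.

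Clustered protocadherins, adhesion proteins encoded in a row on chromosome 18 and partly sharing exons, were counted in the same way. Of 14 tested, 10 were lower in the libraries labelled KD over the average of the times (median -1.93), 6 at control (median -2.16), 3 at 12 h (median -1.54) and 5 at 24 h (median -2.21), and none passed as higher.

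Differences between the lines also followed chromosomes. The median difference of the libraries labelled KD was -0.17 for 895 genes of chromosome 9, -0.19 for 660 genes of chromosome 13 and 0.18 for 510 genes of chromosome 16, and shuffled positions stayed nearer to 0. Chromosomes 9 and 13 held 22.5% of the lower calls with 9.8% of the genes, and chromosome 16 held 10.3% of the higher calls with 3.2%. Of the 96 lower calls on chromosome 13, 22 were histone genes, with no call between the lines at control, and without its 49 histone genes the median was -0.16. The libraries numbered 2 and gene length and expression were argued against, since the chromosome 13 median was -0.18 without those libraries and -0.18 after subtracting the median of genes of like length and expression. Chromosome 2 lay outside the shuffled range by less (0.09, 0.05 and 0.05 by time, 0.06 on average). So did 3 and 5 on average, 3 and 4 at 12 h and 5 and 12 at 24 h (-0.07 to 0.08). Over time within a line, 18 (0.12, KD 12 h) and, by less, 7, 11 and 13 lay outside too. No line difference enters there. On chromosome 4, 48 genes from 149 to 152.3 Mb had a median of -0.38 (17 lower). They held the most extreme window of 25 genes (-0.64). A difference in chromosome copies cannot be told from other causes. All 9 medians of the 3 chromosomes at 3 times lay on the same side and outside the range. But the chromosomes were picked from the average of the same libraries, and no size was set for a copy change. DNA data would decide.

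Bak1 stayed near the counting limit in all 18 libraries and was not lower in those labelled KD. A loss of counts at overlapping genes could account for low counts, since 7.8% of protein-coding genes overlapped on the other strand over at least 90% of their exons reached 10 counts, against 53.3% of genes without an overlap. Genes overlapped over 50 to 90% showed no such loss, with 69.9%, and Bak1 is overlapped over 25.5% of its exon bases. The deposited length of 7221 bases against 2407 in GENCODE M21 leaves open which exons were counted. An exchange of the line labels cannot be told from this gene, since the ratio of count rates of 1.56 had an interval that includes 1.

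Other splits were counted for the remaining comparisons. For the average of the lines, 1 of 60 splits, the real one, was as large (1598 genes, others up to 12). This speaks against random grouping, not chance culture differences. Each comparison of 3 against 3 libraries had 10 splits, too few for a share under 0.05. The real split was the 1 that reached its own count, with 0 genes in the highest of the others: 330, 256 and 223 genes between the lines at control, 12 h and 24 h, 1958, 1211 and 441 for the NC times, and 2558, 1534 and 684 for the KD-labelled times.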
